A study of Mus musculus with 20 samples.

How the data were processed

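Total RNA of the epididymal fat pad was isolated from 20 mice with a lipid tissue kit, amplified and biotinylated with the GeneChip WT PLUS kit and hybridised to arrays, per the labels' protocols. The authors deposited log2 signals per probe set, 22206 for each of the 20 arrays. Per the submitters' processing notes, Transcriptome Analysis Console 4.0.2.15, RMA and the mm10 build were used. RMA usually corrects background, makes the distributions of the arrays alike and summarises probes, so a change shared by most genes would be lost from such values. Background settings, filters and any adjustment for batch were not given in the sources used here. Array medians lay between 6.49 and 6.58, while lower quartiles ranged from 4.59 to 4.92 and upper quartiles from 9.21 to 9.42, so the arrays were alike in their medians but not in their whole distributions. Signals were not converted to an amount of RNA, and low values hold background, so that the difference of a weak gene is compressed.

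Group, batch and replicate number were taken from the sample titles: 10 wt and 10 cre mice, with 5 of each in both batches. The titles call them biological replicates, and each is a mouse. Probe sets were named through the platform annotation: 19572 had 1 symbol, 0 had several and 2634 were unnamed here. All 19572 matched the RefSeq gene table of the mm10 assembly by gene number, which gave current symbols and the coordinates. For gene lists the probe set with the highest mean over all arrays stood for a gene, which left 19505 genes. Of 502 list entries, 454 were measured and 48 had no match, Cd68 and the globin genes among them.

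Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit with genotype and batch as fixed terms, eBayes without trend), with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. The log2 difference is cre minus wt. The selection stated for the study, an unadjusted p under 0.05 and a fold of at least 1.5, was applied to the same fit. The test was checked on 20 simulated data sets of 22206 probe sets, each with 200 changed genes: 33.5%, 78.3% and 98.0% of changes of 1.5-fold, 2-fold and 4-fold were recovered, and 5.2% of the calls were false. A shift of 0.5 put into the macrophage list, with genes drawn independently, was found in 18 of 20 simulations.

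The genes named in the text followed a rule. Tnf and Lyz2 were always named. In each direction up to 10 genes with the smallest p past adjustment were named, filled up with genes of the study's selection by smallest p and said to fail adjustment, leaving out probe sets without a single symbol, predicted Gm genes and Rik clones. Of the up to 3 leading members of each fixed list, those with an unadjusted p under 0.05 are given. Lists of cell types and pathways were tested with camera (preset correlation 0.01, and an estimated correlation beside it) and fry, where at least 5 members were measured, which left 32 of 33 lists. List means per mouse and single genes were tested by two-sided permutation of genotype within batches, with 100000 resamples. The 63504 regroupings within batches allow no p under 3.1e-05. Intervals are 95% intervals of the linear model with genotype and batch. Tests within a single batch enumerated all regroupings. Relations across mice were tested with Pearson's r and Spearman's rho, permuted within the 4 cells of genotype and batch and adjusted over 6 relations. Permutations were run with Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

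The design, the gene lists, the named-gene rule and the alternatives were fixed before the data were examined. The alternatives were no batch term, each batch alone, the replicate number as a block, a trended robust prior, leaving out the 7402 probe sets with the lowest means, quantile normalization of the deposited values again, centring arrays on their medians, array weights, the macrophage list mean as a covariate, another rule for several probe sets of a gene, another fold and leaving out each mouse in turn. After the values were seen, 7 lists of other tissues near the fat pad or in it were written, for seminal vesicle, liver, exocrine pancreas, prostate, bladder epithelium, erythroid precursors and brown adipocytes. As an added alternative, 5 mice were left out whose mean of such a list lay more than 1 log2 unit above every other mouse of their genotype, which kept 8 wt and 7 cre mice.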

Results

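Gene expression was measured in whole epididymal fat pads of 20 male mice with expression arrays, 1 array per mouse. All mice were homozygous for a floxed Tnf gene, which encodes the inflammatory cytokine TNF-α. In 10 mice, called cre, 1 copy of the LyzM-Cre transgene directed deletion of Tnf to macrophages and other myeloid cells. The 10 littermates without Cre, called wt, kept Tnf in all cells. Mice ate chow until 10 weeks of age and then a purified high-fat diet, with 40% of its calories from fat, for 18 weeks, so that tissue was taken at 28 weeks. The arrays were run in 2 batches, each with 5 wt and 5 cre mice. The deposited values were log2 signals of 22206 probe sets, of which 19572 carried 1 gene symbol. Medians per array lay between 6.49 and 6.58, and correlations between arrays lay between 0.93 and 0.989. No pair of arrays held the same values. The number of mice limits the precision of every value. The comparison asks which genes of obese fat differ when deletion of Tnf is directed to macrophages and other myeloid cells. How far macrophages lost TNF-α was not measured in these data.

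Tnf itself was lower in the fat of cre mice. Its log2 signal was 6.66 ± 0.69 (SD, n = 10) in wt and 4.67 ± 0.43 (SD, n = 10) in cre mice, a 3.97-fold lower level in cre (log2 difference −1.99, SE 0.24, limma adjusted p = 0.000822). Each cre mouse lay below each wt mouse, since the highest cre value was 5.34 and the lowest wt value 5.78. The difference was −2.03 in batch 1 and −1.95 in batch 2, and a two-sided permutation test within batches gave p = 3e-05, an estimate from resampling at about 3.1e-05, the smallest that the regroupings allow. The gene lies on chromosome 17, from 35199367 to 35202007 in the mm10 build. The part of Tnf that is floxed was not given in the sources used here, so the probe set may also read sequence outside it. The mean signal in cre was low: the median cre value stood at percentile 22.6 of the values on its array, against percentile 49.5 in wt. Genes of testis and epididymis, not expected in fat, had cre means from 3.38 to 6.70, so background in the cre signal is not excluded, and the fold would then be a lower bound.

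Lyz2, the lysozyme gene of myeloid cells, holds the Cre insert of the LyzM-Cre line (chromosome 10, 117277541 to 117282272, mm10). Its log2 signal was 16.98 ± 0.63 (SD, n = 10) in wt and 15.44 ± 0.73 (SD, n = 10) in cre mice, a difference of −1.55 (SE 0.29), and all 10 cre mice lay below the wt mean. The permutation test of this gene chosen in advance gave p = 0.00015, while limma's p adjusted over all probe sets was 0.176. The difference was −1.80 in batch 1 and −1.29 in batch 2. Leaving out wt replicate 4 brought limma's adjusted p for Lyz2 to 0.0375. Lyz1, the neighbouring lysozyme gene of Paneth cells with a similar sequence, differed by 0.15 (95% interval −0.34 to 0.63, permutation p = 0.529).

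The amount of macrophage RNA differed between fat pads, so both genes were also compared at an equal mean of a list of macrophage genes that holds neither. At equal list mean Tnf differed by −1.84 (95% interval −2.36 to −1.31, permutation p = 3e-05) and Lyz2 by −1.18 (95% interval −1.46 to −0.90, permutation p = 0.00017). The Tnf value was −1.79 in batch 1 and −1.87 in batch 2, and the Lyz2 value −1.21 and −1.15.

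**Figure D1:**
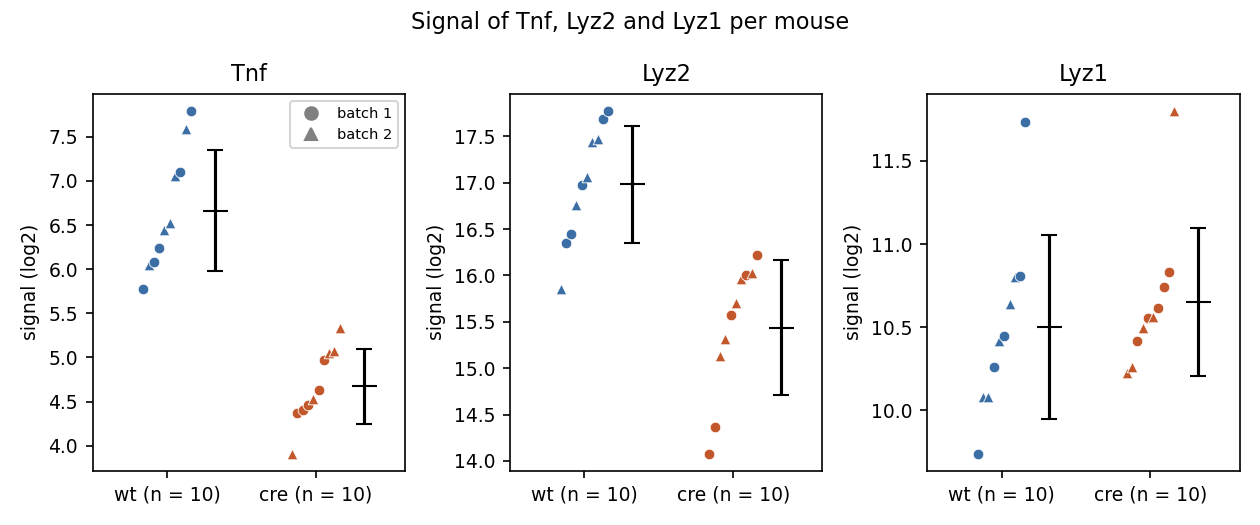
Log2 signal of Tnf, Lyz2 and Lyz1 on the vertical axis, with a point per mouse (blue wt, orange cre, circles batch 1, triangles batch 2) and black bars for the mean ± SD of 10 mice per genotype. All cre values of Tnf lie at or below 5.34 and all wt values at or above 5.78, while the genotypes overlap for Lyz1.

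Across the array, Tnf was the only probe set past an adjusted p of 0.05, with 0 higher and 1 lower in cre mice by limma. An unadjusted p under 0.05 was reached by 1397 probe sets, 720 higher and 677 lower, where 1110 would be reached with no difference at all. The selection that the study states, an unadjusted p under 0.05 and at least 1.5-fold either way, took 232 probe sets, 85 higher and 147 lower in cre, and 205 of them carried a gene symbol. Tnf was the only one of the 232 past adjustment. The excess of lower probe sets was lost without wt replicate 4 (232 higher and 219 lower) or without cre replicate 9 (105 and 104). In each other fit without a single mouse, lower ones outnumbered higher ones. The same test was run on simulated data of this size, each set with 200 changed genes. It recovered 33.5% of genes changed 1.5-fold, 78.3% of those changed 2-fold and 98.0% of those changed 4-fold. The adjustment is stricter where few genes pass, so these shares do not carry over to the real fit with its 1 call. There Lyz2, 2.92-fold lower in cre, did not pass (limma adjusted p = 0.176). The selection grew to 451 probe sets without wt replicate 4 and to 469 without 5 mice set apart by other-tissue lists, a step added after the values were seen, and 157 of the 232 were among the 469. Each of these 5 had a mean of some list of genes of another tissue more than 1 log2 unit above the other mice of its genotype, but kept mice carried liver transcripts too, with list means up to 10.5.

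Among the genes of this selection with the smallest p that were lower in cre mice, none but Tnf passed adjustment (adjusted p from 0.300 to 0.636). Cfp, or properdin, which stabilises the convertase of the alternative complement pathway, differed by −0.83 (SE 0.17), from 12.47 ± 0.43 in wt to 11.63 ± 0.35 in cre (SD, n = 10 each), and all 10 cre mice lay below the wt mean. Bst2, or tetherin, an interferon-induced antiviral membrane protein, differed by −0.59 (SE 0.12), with 9 of 10 cre mice below the wt mean. Rnf31, the catalytic subunit of the linear ubiquitin ligase complex that acts in TNF receptor signalling, differed by −0.71 (SE 0.17). Atp5d, a subunit of mitochondrial ATP synthase, differed by −0.76, and Sos2, a Ras guanine nucleotide exchange factor, by −0.68. Hcfc1r1, Rnf44 and Ap5s1 differed by −0.74, −0.81 and −0.60.

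The corresponding genes higher in cre mice did not pass adjustment either (adjusted p from 0.306 to 0.770). Adamts5, a metalloprotease that cleaves aggrecan, differed by 0.82 (SE 0.22), from 13.55 ± 0.59 in wt to 14.37 ± 0.39 in cre (SD, n = 10 each). Its lowest value, 12.1, was that of wt replicate 6, an array that stood apart from the others. Alkal2, a ligand of the receptor tyrosine kinase ALK, differed by 0.79 (SE 0.23), and Fgf12, an intracellular fibroblast growth factor homologue, by 0.59 (SE 0.17). Spry3 of the Sprouty family of signalling inhibitors differed by 0.65, Skint11 by 0.63, Ccdc148 by 0.63, Gramd2 by 0.62 and Fam131a by 0.59. The olfactory receptor genes Olfr1135 and Olfr1239 differed by 0.64 and 0.59, with wt means of 3.86 and 3.83, which are low on this array.

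Gene lists fixed before the data were examined described cell types and pathways of obese fat. With a preset correlation between genes, limma's camera placed 11 of the 32 lists tested past an adjusted p of 0.05, 5 lower and 6 higher in cre mice. With an estimated correlation 0 lists passed, and each of the 11 had an adjusted p = 0.678 with an estimated correlation. By fry 0 lists passed, with 0.601 as the smallest adjusted p. Nor did any list mean differ between genotypes when mice were permuted within batches (smallest adjusted p = 0.619). Over all 33 lists, 453 genes were measured, 44 of them had an unadjusted p under 0.05, and 0 passed adjustment over all genes or adjusted over the list alone. All differences of lists and of their members given here are therefore values that the spread between mice can hold.

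Macrophage genes had a lower mean in cre mice. All 17 measured members were lower, by −0.51 on average (95% interval over mice −1.36 to 0.33, camera adjusted p = 7.1e-05, adjusted p = 0.678 with an estimated correlation), and the list mean was 13.30 ± 0.73 in wt and 12.78 ± 1.00 in cre (SD, n = 10 each). The difference was −0.86 in batch 1 and −0.17 in batch 2, and from −0.65 to −0.28 when single mice were left out. Most of it came from cre replicates 9 and 7, with list means of 10.7 and 11.4. The other cre mice had 12.5 to 13.8 and the wt mice 12.4 to 14.4. Fcer1g, the Fc receptor gamma chain, differed by −1.25 (SE 0.56), and Tyrobp, a signalling adaptor of myeloid receptors, by −0.80 (SE 0.38). Of the lipid-associated macrophage list, 12 of 15 members were lower (mean −0.22, camera adjusted p = 0.0616), among them the lipid receptor gene Trem2 with −0.78 (SE 0.37). The list came past the camera threshold when any of 9 single mice was left out, with −0.31 (adjusted p = 0.0098, but 0.599 with an estimated correlation) without wt replicate 3, and without the 5 mice set apart by other-tissue lists (−0.24, adjusted p = 0.0283, but 0.550 with an estimated correlation). Genes of classical activation were split 7 higher and 6 lower (mean −0.11, adjusted p = 0.585). Without the same 5 mice that list differed by −0.27 (camera adjusted p = 0.0740, and 0.400 with an estimated correlation). Of genes of alternative activation 6 were higher and 9 lower (mean −0.08, adjusted p = 0.361), among them the transcription factor gene Egr2 with −0.83 (SE 0.38), whose highest value, 13.6, was that of wt replicate 5.

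Interferon-stimulated genes also had a lower mean, with 15 of 17 members lower by −0.32 on average (95% interval −0.67 to 0.02, camera adjusted p = 7.1e-05, adjusted p = 0.678 with an estimated correlation). The difference was −0.34 in batch 1 and −0.30 in batch 2. Irf7, a transcription factor of the interferon response, differed by −0.69 (SE 0.22, adjusted p = 0.0925 adjusted over the list alone), and the oligoadenylate synthetase family genes Oasl2 and Oas1a by −0.74 and −0.47. Without the 5 mice set apart by other-tissue lists the list difference was −0.53, with adjusted p = 0.0704 with an estimated correlation.

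TNF-α acts on cells through NF-κB, and the list of TNF and NF-κB targets differed by −0.11 (95% interval −0.37 to 0.15), with 19 of 28 members lower and a camera adjusted p of 0.157 (0.678 with an estimated correlation). The list difference was −0.24 in batch 1, past the camera threshold there (adjusted p = 0.029, but 0.747 with an estimated correlation), and 0.02 in batch 2. Zfp36, which promotes decay of cytokine mRNA, differed by −0.82 (SE 0.33), while the mitochondrial superoxide dismutase gene Sod2 and the cytokine gene Lif differed by 0.44 and 0.38. The list came past the camera threshold when wt replicate 6 was left out (−0.16, adjusted p = 0.0350), cre replicate 1 (−0.15, adjusted p = 0.0310) or cre replicate 6 (−0.15, adjusted p = 0.0449), but with an estimated correlation the adjusted p was 0.675, 0.675 and 0.682. Leaving out the 7402 probe sets with the lowest means, which removed its dimmest members, gave −0.16 (adjusted p = 0.0340, but 0.693 with an estimated correlation), and leaving out the 5 mice set apart by other-tissue lists −0.15 (adjusted p = 0.0363, but 0.590 with an estimated correlation). Acute phase genes and adipose cytokines were split 5 higher and 6 lower (mean −0.14, adjusted p = 0.506), among the latter the interleukin-1 receptor antagonist gene Il1rn with −0.82 and the acute phase gene Orm2 with −0.77.

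Genes of fat storage had higher means in cre mice, where wt replicates 5 and 6 lowered the wt mean. All 16 measured genes of de novo lipogenesis and triglyceride synthesis were higher, by 0.45 on average (95% interval −0.04 to 0.94, camera adjusted p = 8.3e-06, adjusted p = 0.678 with an estimated correlation). The difference was 0.34 in batch 1 and 0.56 in batch 2, and from 0.29 to 0.53 when single mice were left out. In wt replicates 6 and 5 the lipogenesis list mean was 11.2 and 11.9. The other wt mice had 12.2 to 13.3 and the cre mice 12.6 to 13.3. Acaca, which encodes the acetyl-CoA carboxylase that makes malonyl-CoA, differed by 0.86 (SE 0.27), malic enzyme gene Me1 by 0.80 (SE 0.28) and acetyl-CoA synthetase gene Acss2 by 0.69 (SE 0.25), and wt replicate 6 had the lowest wt values of Acaca and Me1. All 14 measured markers of mature adipocytes were higher, by 0.35 on average (95% interval −0.27 to 0.98, camera adjusted p = 0.0017, adjusted p = 0.678 with an estimated correlation), and 0 of them reached an unadjusted p under 0.05. The adipocyte difference was 0.28 in batch 1 and 0.42 in batch 2, and without wt replicate 6 it was 0.14 (camera adjusted p = 0.139) and without wt replicate 5 it was 0.21 (camera adjusted p = 0.0575). These wt mice had adipocyte list means of 14.1 and 14.8, against 15.8 to 16.7 in the other wt mice and 15.9 to 16.7 in cre mice.

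Of the genes of cholesterol synthesis, 12 of 14 were higher, by 0.32 on average (95% interval −0.06 to 0.69, camera adjusted p = 0.00064, adjusted p = 0.678 with an estimated correlation), 0.25 in batch 1 and 0.38 in batch 2. Without the 5 mice set apart by other-tissue lists the list difference was 0.55, with adjusted p = 0.0704 with an estimated correlation, while the liver list differed by 1.53 in these mice (95% interval −0.10 to 3.16) against 0.98 in all 20. Mevalonate kinase gene Mvk differed by 0.51, lanosterol synthase gene Lss by 0.44 and the desaturase gene Sc5d by 0.49. Fatty acid oxidation (13 of 16 higher, mean 0.17, camera adjusted p = 0.0408), oxidative phosphorylation (15 of 19 higher, mean 0.16, camera adjusted p = 0.0177) and the hypoxia response (12 of 14 higher, mean 0.20, camera adjusted p = 0.0343) followed, each with adjusted p = 0.678 with an estimated correlation. Members with an unadjusted p under 0.05 were the mitochondrial enzyme genes Etfdh, Acadvl and Acadl (0.37, 0.41 and 0.50), the complex I gene Ndufs1 (0.52), the adrenomedullin gene Adm (0.66), Hif1a (0.32) and, lower in cre, Ankrd37 (−0.50). Of these genes, Ndufs1 differed by 0.97 in batch 1 and 0.06 in batch 2, and Hif1a by 0.62 and 0.02. Etfdh differed by 0.36 and 0.39, and Adm by 0.68 and 0.64. For Ndufs1 and Hif1a limma's interaction with batch did not pass adjustment over the named genes (adjusted p = 0.703 each). Oxidative phosphorylation differed by 0.35 in batch 1 and −0.04 in batch 2. The other 2 lists differed by 0.17 and 0.19 in batch 1 and by 0.17 and 0.21 in batch 2. Without wt replicate 6 these 3 lists differed by 0.06, 0.12 and 0.12 and none was past the camera threshold (adjusted p = 0.415, 0.0937 and 0.198), as was so without wt replicate 5 (0.09, 0.08 and 0.15, adjusted p = 0.319, 0.319 and 0.0962). Leaving out single mice ended the call for 9, 3 and 6 of the 20 mice.

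The remaining lists with a lower mean past the camera threshold were mesothelial cells (9 of 10 lower, mean −0.39, adjusted p = 0.0169), immediate early and stress genes (10 of 12 lower, mean −0.21, adjusted p = 0.0188) and the unfolded protein response (9 of 12 lower, mean −0.21, adjusted p = 0.0172), each with adjusted p = 0.678 with an estimated correlation. The mesothelial gene Msln differed by −0.47, the immediate early genes Nr4a1 and Fos by −0.47 and −0.50, and Sdf2l1 of the endoplasmic reticulum by −0.68. In batch 1 the 3 lists differed by −0.39, −0.33 and −0.05, and in batch 2 by −0.39, −0.10 and −0.37. Without wt replicate 6, the array with the highest unfolded protein response mean, that list differed by −0.07 (camera adjusted p = 0.293) and mesothelial genes by −0.21 (camera adjusted p = 0.149). Mesothelial genes also lost the call without cre replicate 5 (−0.30) or cre replicate 10 (−0.30), and immediate early genes without wt replicate 5 (−0.15), cre replicate 9 (−0.14) or cre replicate 10 (−0.19).

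**Figure D2:**
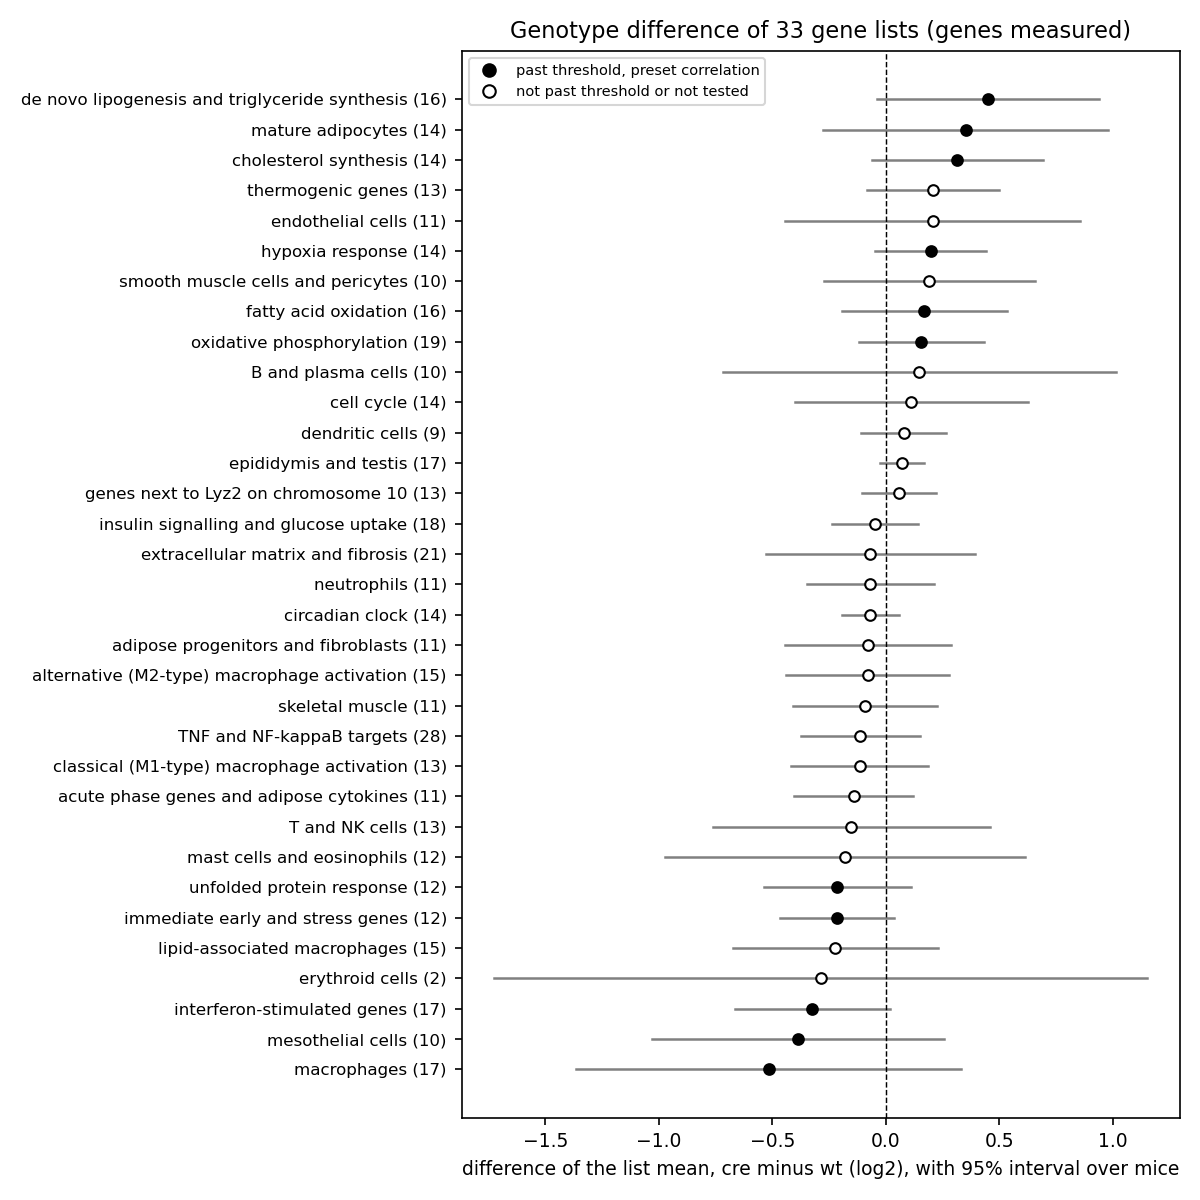
Difference of the mean of each fixed list between genotypes (cre minus wt, log2, horizontal axis), with the number of measured genes in brackets and grey lines for the 95% interval over 20 mice. Filled points mark the 11 lists past the camera threshold with the preset correlation, and all 33 intervals include 0.

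Lists for other constituents of the fat pad did not pass the camera threshold. The mean difference was −0.07 for extracellular matrix and fibrosis genes (adjusted p = 0.734), −0.08 for adipose progenitors and fibroblasts (0.374), 0.21 for endothelial cells (0.212), 0.19 for smooth muscle cells and pericytes (0.0954), −0.15 for T and NK cells (0.221), 0.15 for B and plasma cells (0.359), −0.07 for neutrophils (0.548), 0.08 for dendritic cells (0.512) and −0.18 for mast cells and eosinophils (0.360). Timp1, a metalloprotease inhibitor of the matrix list, differed by −1.29 (SE 0.54), with its lowest value, 4.45, in cre replicate 9. The pericyte gene Rgs5 differed by 0.70 (SE 0.27), with wt replicate 6 and cre replicate 9 as the lowest of their genotypes, and Flt3, the cytokine receptor of dendritic cell precursors, by 0.59 (SE 0.20). Insulin signalling genes (−0.05, adjusted p = 0.798), thermogenic genes (0.21, 0.202), the circadian clock (−0.07, 0.482), the cell cycle (0.11, 0.216), skeletal muscle (−0.09, 0.210), epididymis and testis (0.07, 0.360) and the genes next to Lyz2 (0.06, 0.374) did not pass either. Among their members, the coactivator gene Ppargc1a differed by 0.67, the clock genes Dbp, Nfil3 and Arntl by −0.63, 0.44 and 0.35, the mitotic kinase genes Aurka and Aurkb by 0.44 and 0.41, and the epididymal gene Adam7 by 0.44. A list mean cannot show members that move in opposite directions, as these clock genes did, and 9 insulin signalling genes were higher and 9 lower. The mixed test of fry, which counts both directions, passed 0 lists (smallest adjusted p = 0.917). Of the erythroid list only 2 genes were measured, too few for a test. Single mice decided some of these values. The thermogenic list differed by 0.09 (0.632) without cre replicate 2, whose list mean was 7.10, and by 0.06 (0.805) without the 5 mice set apart by other-tissue lists. Cre replicate 2 is among these 5 and stood out by its brown adipocyte list, of whose 10 genes 6 are also in the fixed lists. A smaller thermogenic difference without it was therefore largely set in advance. Without those 5 mice smooth muscle genes differed by 0.47 (camera adjusted p = 9.6e-07), T and NK cell genes by −0.41 (0.0025) and neutrophil genes by −0.25 (0.0346), but their adjusted p was 0.159, 0.550 and 0.400 with an estimated correlation. At equal macrophage list mean the cell cycle list differed by 0.38 (8.7e-08) and B and plasma cells by 0.41 (0.0110), with 0.313 and 0.576 as adjusted p with an estimated correlation, while in batch 1 alone T and NK cells differed by −0.50 (0.0031, estimated 0.747) and in batch 2 alone B and plasma cells by 0.66 (0.0014, estimated 0.838). The smooth muscle list differed by 0.36 (camera adjusted p = 0.00044) without wt replicate 6, the endothelial list by 0.31 (0.0329) without wt replicate 10, the T and NK cell list by −0.26 (0.0341) without wt replicate 10, the B and plasma cell list by 0.40 (0.0061) without wt replicate 9 and the cell cycle list by 0.25 (0.0053) without wt replicate 5. With an estimated correlation their adjusted p was 0.570, 0.629, 0.629, 0.692 and 0.620.

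Batches and their interaction with genotype were tested with the same model. Between batches 0 probe sets passed adjustment (limma, smallest adjusted p = 0.094) and 127 had an unadjusted p under 0.05, fewer than the 1110 that would be reached with no difference. With a trended, robust variance prior the counts were 0 and 114. For the interaction of genotype and batch 0 probe sets passed (smallest adjusted p = 0.182), 1645 had an unadjusted p under 0.05, and the trended, robust prior gave 0 and 1605.

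Mice of the same genotype and batch differed in how much macrophage RNA their fat held, and 6 relations of the macrophage list mean to other measures were tested over 20 mice, after the mean of each genotype and batch was subtracted. Macrophage genes went with the lipid-associated macrophage list (Pearson's r = 0.916, permutation p = 8e-05, adjusted p = 0.00048, Spearman's rho = 0.889, permutation p = 0.00029) and against mature adipocyte markers (r = −0.529, permutation p = 0.0075, adjusted p = 0.0226, rho = −0.750, permutation p = 0.00019). Without the 2 mice farthest from the median, cre replicates 3 and 9, these r values were 0.863 and −0.543. In batch 1 they were 0.969 and −0.750, and in batch 2 they were 0.621 and −0.313, which did not pass adjustment there (0.445 and 0.744).

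Tnf followed macrophage genes with r = 0.463 (permutation p = 0.0269, adjusted p = 0.0403, rho = 0.487, permutation p = 0.0308), and with r = 0.579 without the 2 farthest mice. It was 0.521 in batch 1 and 0.418 in batch 2, neither past adjustment (0.0778 and 0.744). Oxidative phosphorylation genes went against macrophage genes (r = −0.522, permutation p = 0.0248, adjusted p = 0.0403, rho = −0.579, permutation p = 0.0173). Without the 2 farthest mice r was about as large, −0.478, but with fewer mice not past adjustment (adjusted p = 0.10), and r was −0.740 in batch 1 and −0.134 in batch 2. Extracellular matrix genes (r = 0.539, permutation p = 0.0709, adjusted p = 0.0851, rho = 0.477, permutation p = 0.117) and lipogenesis genes (r = −0.345, permutation p = 0.107, adjusted p = 0.107, rho = −0.466, permutation p = 0.0459) did not pass. Without the 2 farthest mice their r was 0.341 and −0.411. In batch 1 the values were 0.714 and −0.562, and in batch 2 they were −0.144 and −0.145.

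**Figure D3:**
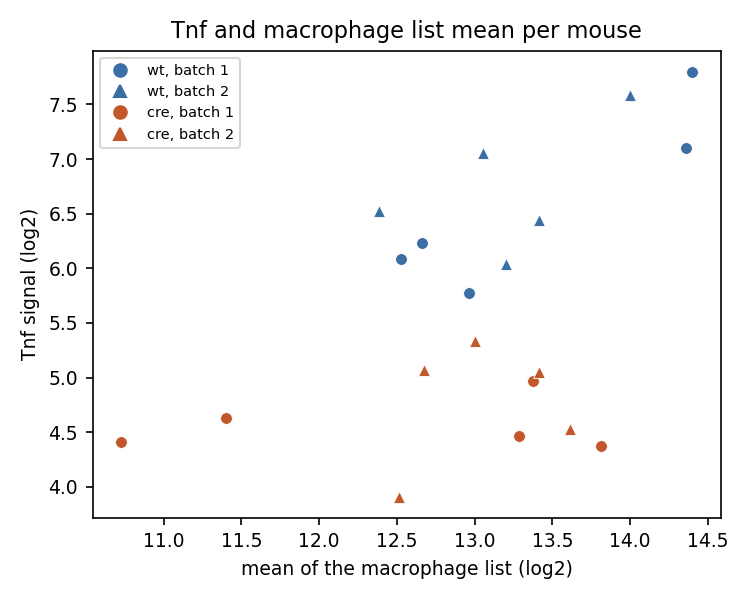
Log2 signal of Tnf (vertical axis) against the mean log2 signal of 17 macrophage genes (horizontal axis), with a point per mouse, coloured by genotype and shaped by batch. The wt points lie above all cre points, and cre points stay at or below 5.34 over the whole range of macrophage means.

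Transcripts of tissues other than fat were present in some fat pads, those of liver in many, measured with lists written after the values were seen. The mean of 12 seminal vesicle genes was 16.8 in wt replicate 6 and at most 6.94 in the other 19 mice. The mean of 20 liver genes ranged from 5.58 to 12.4 over the mice, with the highest value in wt replicate 4. Brown adipocyte and bladder epithelium genes were highest in cre replicate 2 (7.81 and 6.36), with a signal of 12.2 for Ucp1, the uncoupling protein of brown fat, and erythroid precursor genes in cre replicate 9 (7.97). Whether the brown adipocyte genes came from other tissue or from the fat pad itself was not tested. Seminal vesicle genes differed between genotypes by −1.01 (95% interval −3.66 to 1.63, permutation p = 0.802), a direction set by wt replicate 6, without which the difference was 0.22 (95% interval −0.27 to 0.72, permutation p = 0.402). Liver genes differed by 0.98 (95% interval −0.77 to 2.73, permutation p = 0.250), and by 1.55 without wt replicate 4 (95% interval 0.21 to 2.90, unadjusted permutation p = 0.0282). Over all 20 mice 0 of the 7 lists passed adjustment (smallest adjusted p = 0.636).

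**Figure D4:**
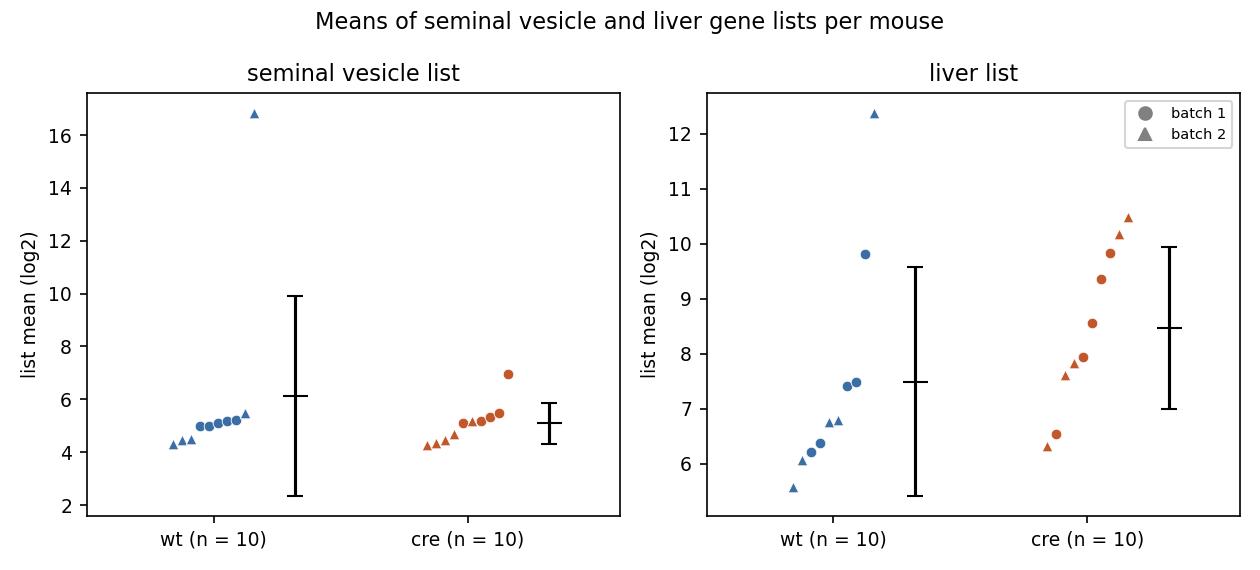
Mean log2 signal of 12 seminal vesicle genes and 20 liver genes (vertical axes), with a point per mouse (blue wt, orange cre, circles batch 1, triangles batch 2) and black bars for the mean ± SD of 10 mice per genotype. In wt replicate 6 the seminal vesicle mean is 16.8, and liver means spread from 5.58 to 12.4.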

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

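The lists of other tissues, and the tests on wt replicates 4 and 6 that use them, were chosen only after the values were seen. Within each genotype of 10 mice, 204 groups of values were searched for a mouse that lay far from the others by Dixon's criterion, and 29 were found, where chance gives about 1 in 20, or 10.2. The groups share mice and some genes and include the lists written after the values were seen, so 10.2 is only a rough mark.

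Fat of wt replicate 6 carried abundant transcripts of the seminal vesicle, a gland next to the epididymal fat pad. Its mean of 12 seminal vesicle genes was 16.8 on the log2 scale, 9.90 above the next mouse, and its Svs5 signal reached 17.3. Seminal vesicle tissue in the sample is a candidate explanation, but the list was written after this mouse was seen, so the gap only restates what prompted it. A poor array is not excluded. The prostate mean of this mouse lay 0.519 above every other mouse and its mean of epididymis and testis genes −0.286 from the highest other mouse, and a poor array need not raise gland genes. No biological explanation was tested, and 0 of the 7 lists differed between genotypes past adjustment (smallest adjusted p = 0.636).

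Liver transcripts were present in graded amounts, with list means from 5.58 to 12.4 over the mice and an albumin gene (Alb) signal from 7.85 to 18.9. In wt replicate 4 the liver mean was 12.4, 1.89 above the next mouse, and the exocrine pancreas mean was 6.85, 1.45 above the next. The other 19 mice spanned 4.83 to 5.40 for the pancreas list. The smaller gap, 1.4518, stayed short of 2 log2 units, but that bound was set after the values were seen and excludes nothing. Liver and pancreas RNA in this mouse stays open, as does the origin of the liver transcripts of the other mice. Without this mouse the liver list differed between genotypes by 1.55 (95% interval 0.21 to 2.90).

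Other mice far from the rest of their genotype are given as values. In cre replicate 3 the seminal vesicle mean was 6.94. In cre replicate 2 the brown adipocyte mean was 7.81, the fixed thermogenic list mean 7.10, with a Ucp1 signal of 12.2, and the bladder epithelium mean 6.36. In cre replicate 9 the mean of the 2 measured erythroid genes was 14.6 and that of the erythroid precursor list 7.97, the neutrophil mean 6.26 and the immediate early gene mean 8.23, with Timp1 at 4.45 and Rgs5 at 10.2. Its mean correlation with the other arrays was 0.966, and that of wt replicate 6 was 0.949. In wt replicate 6 the second principal component score was −87.7, the prostate mean 5.73, the smooth muscle and pericyte mean 10.1, the unfolded protein response mean 12.7, the alternative macrophage activation mean 8.61 and the mean of genes next to Lyz2 9.05. Single genes of that mouse were Adamts5 at 12.1, Acaca at 9.17, Me1 at 12.4, Rgs5 at 9.46 and Sdf2l1 at 11.1. In wt replicate 4 the exocrine pancreas mean of 6.85 was far from the other wt mice. The Egr2 signal was 13.6 in wt replicate 5, the neutrophil mean 6.49 in wt replicate 10, the skeletal muscle mean 7.40 in wt replicate 7 and the unfolded protein response mean 11.6 in cre replicate 5.

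The lower Lyz2 signal of cre mice was set against 2 explanations. If it came only from fewer macrophages, the difference at an equal macrophage list mean would include 0, but the upper end of its 95% interval was −0.898, which argues against this. In the LyzM-Cre line the insert takes the place of 1 of the 2 Lyz2 copies, which would lower the signal by 1 log2 unit. The difference at equal list mean was −1.1792 with an interval that includes −1, so loss of 1 copy may account for it, as a hypothesis. Cross-reading with Lyz1 would pull the difference toward 0 and was not tested. Lyz1 signals were 9.74 to 11.8, against 14.1 to 17.8 for Lyz2, so the pull would be small if both probe sets read alike.

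Differences between the batches were small. The median absolute log2 difference between batches was 0.0613, and only 1 of 100 splits that kept genotypes balanced, the labelled one itself, was as small, with 0.0933 to 0.159 in the others. Values that were adjusted for batch before deposit may look like this. Removal of batch means alone would leave no difference between batches in this balanced design. The median of 0.0613 argues against it as the last step. Bst2 and Sos2, named above, differed by −0.74 and −0.60 (batch 2 minus batch 1), neither past adjustment. An adjustment of another kind may make p-values across genotypes slightly too small. No biological explanation was tested. Between batches 0 genes passed adjustment (127 at an unadjusted p under 0.05), where each of 99 other splits gave at least 237 at that level and at most 1 past adjustment. For the interaction with genotype 0 genes passed (1645 at an unadjusted p under 0.05), and the highest other split gave 162. Since the real counts are 0, 100 of 100 splits reach them by construction, which says nothing about chance.

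The real count of 1 gene changed between genotypes was reached by 4 of 100 splits of the 20 mice within batches. These 4 include the real split, and the others gave 1, 8 and 44 genes, so this count alone does not exclude chance. For Tnf itself, the permutation test within batches gave p = 3e-05. The highest count, 44, may point to a structure of the mice apart from genotype, and which mice it would part was not tested. Chance cannot be excluded for the study's selection, where 26 of 100 splits reached the real 232 probe sets and the highest other gave 1043. The same holds for the fixed lists, where 23 of 100 splits reached the real 11 lists, the highest other gave 16 and the median of the others was 8.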

How the results depend on the processing

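Leaving out the 5 mice set apart by other-tissue lists was chosen after the data were seen, and all other alternatives before. The 57 single genes named beside Tnf and Lyz2 kept their direction and their side of the threshold in all 620 values computed under 11 other settings and in all 1140 values computed without 1 mouse. No batch term, a trended robust prior, centring of arrays and the mean of all probe sets changed no call, and quantile normalization again changed 1 relation across mice. Leaving out the 7402 dimmest probe sets brought TNF and NF-κB targets past the threshold (−0.16). Cd68 was not measured, so only Adgre1 was run as a single-gene covariate, and the macrophage list has no value at its own equal mean. List calls here use the preset correlation; with an estimated one 0 lists passed in all 31 other settings (smallest adjusted p = 0.0704). Where no reason is given, the cause was not tested.

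In batch 1 alone, with fewer mice, 0 genes passed adjustment, the study's selection took 946 probe sets, Tnf differed by −2.03 (adjusted p = 0.676), 7 lists passed, with T and NK cells and TNF and NF-κB targets gained and adipocytes, cholesterol synthesis, fatty acid oxidation, immediate early genes, hypoxia and the unfolded protein response lost, and B and plasma cells (−0.36), neutrophils (0.0204) and dendritic cells (−0.0121) reversed. In batch 2 alone, 0 genes passed, the selection took 568, Tnf differed by −1.95 (adjusted p = 0.837) and 6 lists passed, with B and plasma cells gained and macrophages (−0.17), fatty acid oxidation, oxidative phosphorylation, mesothelial cells, immediate early genes and hypoxia lost. There the lists of alternative macrophage activation (0.0098), TNF and NF-κB targets (0.0156), oxidative phosphorylation (−0.0357), extracellular matrix (0.12), T and NK cells (0.20), mast cells and eosinophils (0.0255), skeletal muscle (0.0244) and genes next to Lyz2 (−0.0415) reversed.

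Replicate numbers did not pair the mice: 4 of 10 same-numbered pairs had deviations correlated above 0.1 (from −0.30 to 0.34), and 3 of 20 arrays correlated best with their own number. With the number as a replicate block, which leaves fewer degrees of freedom, 0 genes passed, and Tnf differed by −1.99 with an adjusted p of 0.0568. It changed no other call.

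With array weights 6 lists passed, with smooth muscle (0.31, adjusted p = 0.0074) and the cell cycle (0.23, 0.0113) gained and adipocytes (0.12), fatty acid oxidation (0.0717), oxidative phosphorylation (0.0860), mesothelial cells (−0.27), immediate early genes (−0.16), hypoxia (0.10) and the unfolded protein response (−0.13) lost, and mast cells and eosinophils reversed (0.0366). With the macrophage list mean as a covariate 2 genes passed, Tnf and Lyz2 (−1.18, adjusted p = 0.00081), and 6 lists, with the cell cycle and B and plasma cells gained and adipocytes (0.16), fatty acid oxidation (0.0844), oxidative phosphorylation (0.0650), immediate early genes (−0.0897), hypoxia (0.13) and the unfolded protein response (−0.18) lost. Classical macrophage activation (0.0311), lipid-associated macrophages (0.0263), extracellular matrix (0.0891), progenitors and fibroblasts (0.0619), endothelial cells (−0.00171), T and NK cells (0.0807) and mast cells and eosinophils (0.17) reversed. With an estimated correlation 0 lists passed in all mice. A fold of at least 1.2 selected 1364 probe sets, by its wider limit. Without the 5 mice set apart by other-tissue lists the selection took 469, 11 lists passed. Gained were lipid-associated macrophages, TNF and NF-κB targets, smooth muscle, T and NK cells and neutrophils, and lost were fatty acid oxidation, oxidative phosphorylation, immediate early genes, hypoxia (0.15) and the unfolded protein response (−0.0828). There B and plasma cells (−0.25) and dendritic cells (−0.0211) reversed.

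Leaving out each mouse gave 1 to 2 genes past adjustment (2 without wt replicate 4), 180 to 451 probe sets in the selection (451 without wt replicate 4) and 7 to 14 lists (7 without wt replicate 5). Lyz2 ranged from −1.69 to −1.39 and passed without wt replicate 4 (adjusted p = 0.0375). Of the 11 lists past the threshold, macrophages, interferon-stimulated genes, lipogenesis and cholesterol synthesis, 4 lists, kept the call without each mouse and 7 lost it without some mouse, while 7 other lists gained it. Lists that reversed without a mouse ranged from −0.15 to 0.0539 for extracellular matrix (highest without cre replicate 9), −0.15 to 0.0095 for progenitors and fibroblasts (without wt replicate 5), −0.26 to 0.0189 for T and NK cells (without wt replicate 9), −0.0305 to 0.40 for B and plasma cells (lowest without cre replicate 2), −0.14 to 0.0300 for neutrophils (without wt replicate 10) and −0.13 to 0.0317 for skeletal muscle (without wt replicate 7).

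Of the relations to the macrophage list by Pearson's r, Tnf did not pass in batch 1 (r = 0.521), batch 2 (0.418), wt (0.781) or cre mice (0.144) alone, nor adipocytes in batch 2 (−0.313) or wt mice (−0.534). Oxidative phosphorylation did not pass without the 2 farthest mice (−0.478), in batch 2 (−0.134), wt (−0.468) or cre mice (−0.583), nor lipid-associated macrophages in batch 2 (0.621). Extracellular matrix passed with values not centred (0.557) and in cre mice (0.884, against 0.0875 in wt mice) and reversed in batch 2 (−0.144), and lipogenesis passed with quantile normalization again (−0.451). By Spearman's rho adipocytes passed in wt mice (−0.794, adjusted p = 0.0452) but not in cre mice (−0.770, 0.0511), where lipid-associated macrophages (0.903) and extracellular matrix (0.879) did not pass either (0.0712 each). Not centred, Tnf (0.332), oxidative phosphorylation (−0.475) and matrix (0.361) did not pass, nor Tnf without the 2 farthest mice (0.550), and lipogenesis passed (−0.585), as in batch 1 (−0.697).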

Other observations

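Thermogenic and clock genes did not pass the camera threshold as lists. The means of thermogenic genes were 5.87 ± 0.18 in wt and 6.08 ± 0.38 in cre mice (SD, n = 10 each), where cre replicate 2 had 7.10 and the other cre mice 5.75 to 6.24. The thermogenic difference of 0.21 fell to 0.0862 without that mouse. The means of clock genes were 9.20 ± 0.11 and 9.13 ± 0.15. Dbp was lower and Nfil3 and Arntl higher in cre mice, and a list mean cannot show members that move in opposite directions. The genes next to Lyz2 on chromosome 10, where sequence of the strain that carried the Cre insert could remain, had means of 8.50 ± 0.22 and 8.56 ± 0.09, and 0 of 13 members had an unadjusted p under 0.05. Their difference was 0.16 in batch 1 alone and −0.0415 in batch 2 alone.

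A hypothesis set before its result was seen was that Cre removes the macrophage part of Tnf in whole fat, so that Tnf would follow macrophage genes in wt but less in cre mice. Per log2 unit of the macrophage list mean, Tnf rose by 0.73 (SE 0.22, n = 10) in wt and by 0.06 (SE 0.16, n = 10) in cre mice, and a permutation test of the difference of 0.67 gave p = 0.0404. This is consistent with the hypothesis, but the result depends on single mice. Leaving out each mouse in turn gave p from 0.0195 to 0.138, at or above 0.05 in 9 of 20 fits, with the highest values without cre replicate 7 (0.138) and cre replicate 9 (0.129). The low Tnf signal in cre mice, with a median at percentile 22.6 of the array, may also flatten the slope there, which was not tested.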
